A study of Homo sapiens with 60 samples.

How the data were processed

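RNA was sequenced from SW1783 cells grown in Leibovitz's L-15 medium with 10% FBS and treated for 24 h. Per the labels, total RNA with a RIN above 7 (1 µg) went into the MGIEasy RNA Directional library kit and was read as 100 bp paired ends on an MGIseq instrument. The deposited table holds expected counts per gene, estimated by the authors with RSEM 1.3.3 and not normalised between samples; the processing notes also name FastQC 0.11.9, Trim Galore 0.6.5, STAR 2.7.3a and the genome build GRCh38. The strand setting of the counting is not given in the sources used here. Of the values, 9.5% were not whole numbers at a tolerance of 1e-06, so they were rounded. The table has 279 columns, of which 60 belong to the given samples, and the other 219 were not used here. Of 60675 genes, 41706 carried a symbol, 57055 were found in GENCODE 29 and 17376 had no count in any library used; the 18969 genes without a symbol held 0.413% of the counts.

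The vehicle is DMSO, given as 0.1% in the sample labels and as 2% in the series text, and which was used could not be settled. For the extract and drug samples no DMSO content was recorded here, so whether they held the same solvent is not known. The series text also says that extracts reaching IC20 below 500 µg/mL were given at lower doses, while the sample labels give 500, 100 and 20 µg/mL for all extracts here. Samples were grouped by treatment and dose into 22 groups, with 3 libraries in 16 groups and 2 in 6 groups. Total counts ran from 19.45 to 30.87 M counts per library.

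Genes were kept by filterByExpr of edgeR 4.0.16 (minimum count 10, minimum total 15), which left 17919 genes. Counts were scaled by TMM and fitted in 1 quasi-likelihood model of all 60 libraries with 1 coefficient per group and robust estimation; the common biological coefficient of variation was 0.051 and the median prior degrees of freedom were 13.4. Each contrast was tested with edgeR's quasi-likelihood F-test, two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. The SE of a log2 fold change was taken as its size divided by the square root of F. A prior count of 2 was used for log CPM values, as in camera and the principal components, and not for the log2 fold changes. The comparisons were 3 drugs and 6 extracts at 3 doses against vehicle, wortmannin against LY294002, and the high against the low dose of each extract, 28 in all. All comparisons with vehicle share the same vehicle libraries and are not independent of each other.

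Before the data were examined, 24 gene lists with 417 members were fixed, all of which were found, 2 of them by a synonym. They cover cholesterol synthesis, fatty acid synthesis, FOXO targets, lysosome, NRF2 targets, ATF4 targets, ER stress, heat shock, hypoxia and glycolysis, AhR targets, metallothioneins, p53 targets, S phase, mitosis, NF-kB inflammation, interferon response, early response to growth factors (ERK), glucocorticoid response, matrix with YAP and TGF-beta targets, cytosolic ribosomal proteins, the mitochondrial genome, astroglial markers, markers of other neural cells, and markers of epithelial, blood and endothelial cells. NQO1 is on the AhR and NRF2 lists, SLC7A11 on the NRF2 and ATF4 lists, ALDOC on the hypoxia and astroglial lists, and PDK4 on the FOXO and glucocorticoid lists. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation and fry as alternatives, adjusted over the 24 lists of a comparison.

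The rule for named genes was also fixed before the data were examined. For drugs and high doses it took the 5 largest rises and 5 largest falls among called genes with a mean of at least 5 CPM in a group, an informative symbol and every treated library on the same side of every vehicle library, then up to 3 members with the smallest p from each list that passed camera or had at least 1 in 3 of its measured members called, to a cap of 30 genes. For the contrast of both inhibitors it took the 5 largest in each direction, and for lower doses and dose contrasts the 2 largest.

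Alternatives were RLE size factors, no filter on low counts, the replicate number as a block, a fit of the 2 groups alone, the DESeq2 1.42.0 Wald test, leaving out each library in turn and, added after the data were seen, leaving out 5 libraries that stood apart: replicate 1 of peony high, atractylodes high and ginseng low, replicate 3 of licorice medium and replicate 2 of angelica low. For comparisons of 3 against 3 libraries all 10 splits were fitted. The pipeline was tested on simulated data with 50 changed genes at each fold and 17262 genes tested: for 3 against 3 libraries 34, 40, 48 and 49 were recovered at folds of 1.25, 1.5, 2 and 4, for 2 against 3 libraries 30, 41, 43 and 50, with 11 and 7 unchanged genes called and 0 in the wrong direction. In those data the p of camera was 9.47e-111 and 2.26e-99 for a changed list and 0.532 and 0.736 for an unchanged list (limma, a model across all genes). The simulated genes were drawn independently, so these values cannot show how camera at the preset correlation behaves on correlated genes. R 4.3.3, Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used.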

Results

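Gene expression was measured by RNA sequencing in SW1783, a human astrocytoma cell line, after 24 h of treatment. The treatments were hot-water extracts of 6 medicinal materials, 3 drugs and the solvent DMSO as vehicle. The extracts came from Poria Cocos, Atractylodis Rhizoma, Glycyrrhizae Radix (licorice), Panax Ginseng, Angelicae Gigantis Radix and Paeoniae Radix (peony), named poria, atractylodes, licorice, ginseng, angelica and peony here. Each extract was given at 500, 100 and 20 µg/mL, called the high, medium and low dose. The drugs, at 10 µM, were wortmannin and LY294002, which inhibit PI3-kinase, and thioridazine, an antipsychotic of the phenothiazine class. The 60 libraries formed 22 groups, 16 of 3 libraries and 6 of 2 libraries, the latter being the angelica and peony groups, whose replicate 3 was not analysed here. Library totals ranged from 19.45 to 30.87 M counts with a median of 26.045 M, and from 27.37 to 29.87 M in the vehicle libraries. Among 17919 genes tested, a gene is called changed at an adjusted p under 0.05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Changes are log2 fold changes ± SE, levels are mean CPM ± SD, and a p given for a gene list comes from camera. Positions are on GRCh38 as annotated by GENCODE 29. The largest changes are named among genes of at least 5 CPM by the rule given with the processing. List members beyond that rule, cell type markers and TXNIP where it was not among the named genes were chosen after their values were seen. Whether replicates were separate cultures is not given in the sources used here, so the p-values measure the spread between these libraries. The titles of all samples, vehicle included, name the same batch, A. The sample codes, however, put the vehicle in a set of its own, so that set and treatment cannot be told apart in comparisons with vehicle. The high and the low dose of an extract share a set.

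**Figure D1:**
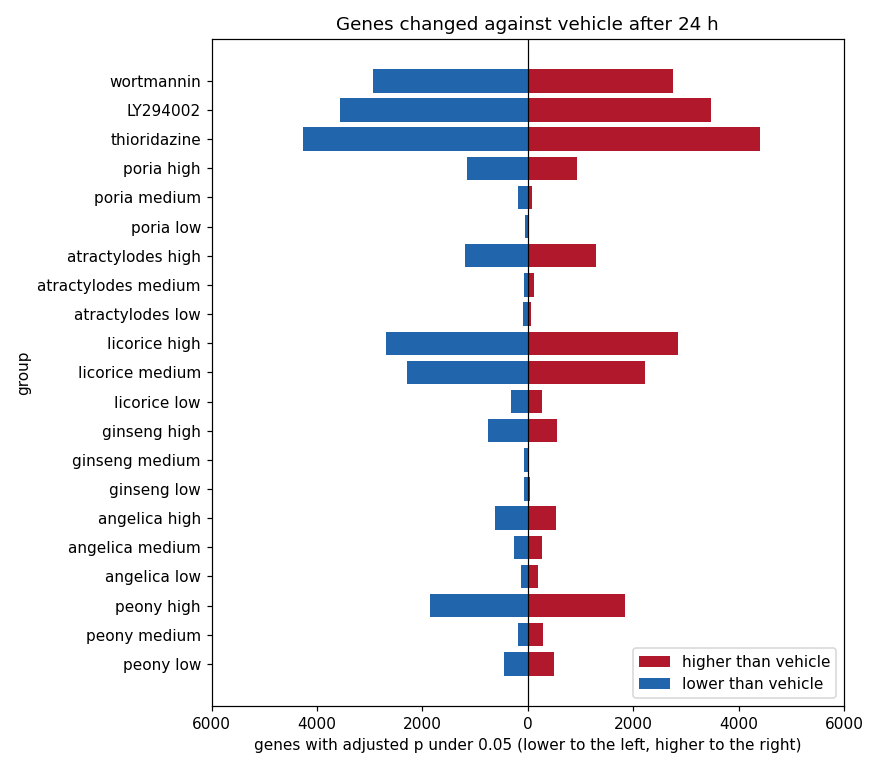
Numbers of genes with an adjusted p under 0.05 in each treatment group against vehicle, higher genes drawn to the right in red and lower genes to the left in blue. The bars are longest for thioridazine, with 4406 higher and 4269 lower genes, and shortest for poria at the low dose, with 21 higher and 54 lower.

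The first question was what each drug changed against vehicle. In cells given wortmannin, genes of mitosis and DNA replication fell and genes known as targets of FOXO transcription factors, which PI3-kinase signalling holds out of the nucleus, rose. Of the 20 measured mitosis genes 18 fell (adjusted p = 3.48e-12, and 0.00137 with an estimated correlation), among them CDC20, an activator of the anaphase-promoting complex, at -0.71 ± 0.05 from 261 ± 12 to 160 ± 3.8 CPM (SD, n = 3). Of 20 S-phase genes 14 fell (adjusted p = 2.12e-07, and 0.0675 with an estimated correlation), including RRM2, a subunit of ribonucleotide reductase, at -0.56 ± 0.04. Of 20 FOXO targets 12 rose and 2 fell (adjusted p = 4.71e-05, and 0.00137 with an estimated correlation), with TXNIP, an inhibitor of thioredoxin and of glucose uptake, at 1.15 ± 0.09 and CCNG2, a cyclin linked to cell cycle arrest, at 0.70 ± 0.06. Lysosomal genes rose in 13 and fell in 3 of 24 cases (adjusted p = 7.59e-05, and 0.0675 with an estimated correlation), among them the protease CTSB at 0.54 ± 0.04. Of 5 metallothionein-list genes 4 rose (adjusted p = 0.00289, and 0.104 with an estimated correlation), MT2A from 478 ± 39 to 1290 ± 42 CPM, although reads of this family can be shared between its similar copies. Growth-factor early-response genes rose in 11 and fell in 3 of 20 cases (adjusted p = 0.00397, and 0.132 with an estimated correlation), DUSP6, a phosphatase acting on ERK, at 0.62 ± 0.06. Adjusted over the list alone, 19 mitosis and 14 S-phase genes fell, and 12 FOXO, 13 lysosomal, 4 metallothionein and 11 early-response genes rose.

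The largest rises after wortmannin were KRTAP1-5 (2.23 ± 0.14, a keratin-associated gene with similar copies, so its level is uncertain), TMEM132B (1.98 ± 0.17) and IGFBP1 (chromosome 7, 45888357 to 45893668), a secreted binder of insulin-like growth factors that FOXO proteins induce, which rose by 1.83 ± 0.08 from 21.6 ± 0.96 to 77.0 ± 4.7 CPM. The chemokine CXCL12 (-1.38 ± 0.08), smooth muscle actin ACTA2 (-1.32 ± 0.06) and heme oxygenase HMOX1 (-1.28 ± 0.07) fell most. Hypoxia and glycolysis genes fell in 10 and rose in 1 of 20 cases (adjusted p = 0.0161, and 0.132 with an estimated correlation). Heat shock genes fell in 6 and rose in 1 of 12 (adjusted p = 0.00434, and 0.123 with an estimated correlation), HSP90AA1 at -0.51 ± 0.05. Cholesterol synthesis genes rose in 12 and fell in 4 of 25 cases (adjusted p = 0.036, and 0.289 with an estimated correlation). When adjusted over the list alone, 11 hypoxia and 6 heat shock genes fell and 13 cholesterol genes rose. In all, 2754 genes rose and 2932 fell, of which 205 and 51 changed at least 2-fold.

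LY294002 moved many of the same lists. FOXO targets rose in 14 and fell in 2 of 20 cases (adjusted p = 6.29e-08, and 2.34e-05 with an estimated correlation), with TXNIP at 1.68 ± 0.08 and HBP1, a transcriptional repressor, at 0.94 ± 0.05. Mitosis genes fell in 16 of 20 cases (adjusted p = 6.29e-08, and 0.0112 with an estimated correlation), CDC20 at -0.66 ± 0.05. S-phase genes fell in 14 of 20 (adjusted p = 1.13e-07, and 0.0516 with an estimated correlation), with the replication licensing factor CDC6 at -0.70 ± 0.04. NF-kB inflammatory genes fell in 10 and rose in 1 of 18 cases (adjusted p = 7.64e-06, and 0.000286 with an estimated correlation): the neutrophil chemokine CXCL8 (chromosome 4, 73740506 to 73743716) fell by 1.92 ± 0.13 from 11.1 ± 1.4 to 2.92 ± 0.14 CPM, and BIRC3 and TNFAIP3, regulators of this pathway, changed by -1.56 ± 0.10 and -1.02 ± 0.08. Hypoxia and glycolysis genes fell in 14 and rose in 1 of 20 cases (adjusted p = 5.87e-05, and 0.0112 with an estimated correlation), with hexokinase HK2 at -0.62 ± 0.06. Lysosomal genes rose in 12 and fell in 4 of 24 cases (adjusted p = 0.00145, and 0.102 with an estimated correlation). NRF2 targets rose in 11 and fell in 3 of 20 (adjusted p = 0.0237, and 0.329 with an estimated correlation). Metallothionein-list genes rose in 4 of 5 (adjusted p = 0.00152, and 0.0759 with an estimated correlation). Heat shock genes fell in 7 and rose in 2 of 12 cases (adjusted p = 0.023, and 0.213 with an estimated correlation). For these lists, adjusted over the list alone, 15 FOXO, 12 lysosomal, 11 NRF2 and 4 metallothionein genes rose, and 17 mitosis, 15 S-phase, 12 NF-kB, 15 hypoxia and 9 heat shock genes fell.

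The largest rises after LY294002 included YPEL1 (3.06 ± 0.21) and KLHL24, which rose by 1.86 ± 0.06 from 18.9 ± 0.52 to 68.8 ± 2.0 CPM. The histone gene H4C15 rose by 1.90 ± 0.50, but it has similar copies, so its level is uncertain, and its adjusted p was 0.0974 when edgeR was fitted to these 2 groups alone. The thrombin receptor gene THBD (-1.60 ± 0.12), the protease inhibitor gene SERPINB2 (-1.58 ± 0.11) and the hyaluronan synthase gene HAS2 (-1.55 ± 0.14) were among the largest falls. In all, 3476 genes rose and 3562 fell, of which 324 and 157 changed at least 2-fold.

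Because both inhibitors were given at the same dose and time, their difference was tested directly, and 1575 genes were higher and 1356 lower with wortmannin than with LY294002. NRF2 targets, genes of antioxidant defence, were lower with wortmannin in 12 and higher in 2 of 20 cases (adjusted p = 1.57e-10, and 0.00149 with an estimated correlation); HMOX1 had 34.7 ± 0.43 CPM with wortmannin and 81.7 ± 4.4 with LY294002 (-1.23 ± 0.07). FOXO targets were lower with wortmannin in 9 of 20 cases (adjusted p = 9.2e-06, and 0.000322 with an estimated correlation), TXNIP at -0.53 ± 0.08. NF-kB inflammatory genes were higher with wortmannin in 8 of 18 cases (adjusted p = 1.15e-09, and 3.5e-06 with an estimated correlation), CXCL8 at 1.66 ± 0.14 and TNFAIP3 at 0.92 ± 0.08, and hypoxia genes were higher in 7 and lower in 1 of 20 (adjusted p = 0.00613, and 0.0982 with an estimated correlation), VEGFA at 0.38 ± 0.04. Adjusted over the list alone, 13 NRF2 and 10 FOXO genes were lower and 8 NF-kB and 7 hypoxia genes higher. The secretogranin genes SCG5 (1.36 ± 0.12) and SCG2 (1.34 ± 0.11) were among the genes higher with wortmannin, and the nuclear RNA NEAT1 (-0.98 ± 0.13) and the mitochondrial carrier gene UCP2 (-0.96 ± 0.11) among those lower.

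Thioridazine changed 8675 genes, 4406 up and 4269 down, with 788 and 424 changed at least 2-fold. All 25 measured cholesterol synthesis genes rose (adjusted p = 4.11e-32, and 5.4e-08 with an estimated correlation): INSIG1, which restrains sterol synthesis and is induced when sterols are low (chromosome 7, 155297776 to 155310235), went from 171 ± 2.5 to 924 ± 9.1 CPM (2.44 ± 0.05, SD, n = 3), and HMGCS1, an early enzyme of the pathway, from 63.7 ± 1.9 to 306 ± 9.7 CPM (2.27 ± 0.05). Fatty acid synthesis genes rose in 12 and fell in 1 of 13 cases (adjusted p = 2.47e-11, and 0.00097 with an estimated correlation), with the desaturase SCD at 2.39 ± 0.05. Lysosomal genes rose in 23 of 24 cases (adjusted p = 2.67e-23, and 1.62e-06 with an estimated correlation), GPNMB from 32.8 ± 1.5 to 204 ± 6.2 CPM and the cholesterol exporter NPC1 at 1.45 ± 0.05. Targets of ATF4, the transcription factor of amino acid and integrated stress responses, rose in 19 of 20 cases (adjusted p = 2.09e-20, and 3.15e-05 with an estimated correlation), with NUPR1 at 3.35 ± 0.09 and asparagine synthetase ASNS at 1.85 ± 0.05. S-phase genes fell in 19 of 20 cases (adjusted p = 2.83e-19, and 0.000487 with an estimated correlation), RRM2 at -2.04 ± 0.04. Mitosis genes fell in 20 of 20 (adjusted p = 4.01e-18, and 4.88e-05 with an estimated correlation), TPX2, a spindle assembly factor, at -0.87 ± 0.04. NRF2 targets rose in 17 of 20 cases (adjusted p = 4.05e-09, and 0.00225 with an estimated correlation), with the ferritin chain gene FTH1 at 1.26 ± 0.06. When adjusted over the list alone, 25 cholesterol, 12 fatty acid, 23 lysosomal, 19 ATF4 and 17 NRF2 genes rose, and 19 S-phase and 20 mitosis genes fell.

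Genes of matrix and of YAP and TGF-beta signalling fell in 14 and rose in 2 of 20 cases after thioridazine (adjusted p = 4.56e-07, and 0.0139 with an estimated correlation), ACTA2 from 143 ± 3.8 to 27.5 ± 3.0 CPM (-2.38 ± 0.07). Hypoxia genes fell in 12 and rose in 3 of 20 (adjusted p = 6.35e-05, and 0.00711 with an estimated correlation). FOXO targets rose in 13 and fell in 3 of 20 (adjusted p = 4.96e-05, and 0.000618 with an estimated correlation). ER stress genes rose in 10 and fell in 1 of 16 (adjusted p = 0.00132, and 0.201 with an estimated correlation). Genes targeted by p53 rose in 8 and fell in 4 of 15 (adjusted p = 0.00672, and 0.0502 with an estimated correlation). AhR targets rose in 5 of 7 (adjusted p = 0.0181, and 0.0756 with an estimated correlation). Heat shock genes fell in 9 and rose in 1 of 12 (adjusted p = 0.00139, and 0.0502 with an estimated correlation). Metallothionein-list genes rose in 4 of 5 (adjusted p = 0.0351, and 0.177 with an estimated correlation). For these lists, adjusted over the list alone, 14 matrix, 12 hypoxia and 9 heat shock genes fell, and 13 FOXO, 11 ER stress, 8 p53, 6 AhR and 4 metallothionein genes rose. Among the largest rises were KCP (5.46 ± 0.22), the stress-induced cytokine GDF15 (chromosome 19, 18374731 to 18389176; 5.29 ± 0.10, from 4.36 ± 0.75 to 170 ± 19 CPM) and the proton pump subunit ATP6V0D2 (4.95 ± 0.32). HAS2 (-2.55 ± 0.15) and the chemokine CCL2 (-2.54 ± 0.10) fell most. The list of epithelial, blood and endothelial markers did not pass the camera test (adjusted p = 0.0887), although within it KRT18 changed by -1.78 ± 0.05 and CD68, which is also a lysosomal protein, by 0.45 ± 0.08.

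The second question was what each extract changed and how the change depended on dose. Poria at the high dose raised TXNIP (chromosome 1, 145992435 to 145996600), a gene induced by glucose through the MondoA and ChREBP factors, from 10.7 ± 0.33 to 206 ± 5.3 CPM (4.27 ± 0.08, SD, n = 3), and its relative ARRDC4 (chromosome 15, 97960698 to 97973838) from 6.67 ± 0.32 to 32.9 ± 2.2 CPM (2.30 ± 0.09). At the medium dose TXNIP rose by 1.44 ± 0.09, and at the low dose it had 10.1 ± 0.58 CPM (-0.08 ± 0.10, adjusted p = 0.77). ER stress genes fell in 13 of 16 cases (adjusted p = 2.79e-26, and 0.000241 with an estimated correlation): the chaperone HSPA5 (chromosome 9, 125234853 to 125241330) fell by 0.72 ± 0.05 from 3530 ± 120 to 2140 ± 59 CPM, and HERPUD1, which acts in degradation of ER proteins (chromosome 16, 56932048 to 56944863), fell by 1.10 ± 0.12. NRF2 targets rose in 19 of 20 cases (adjusted p = 4.91e-44, and 5.38e-09 with an estimated correlation), with the quinone reductase NQO1 at 0.98 ± 0.05 and the reductase AKR1B10 at 1.41 ± 0.11. AhR targets, a list that shares NQO1 with the NRF2 list, rose in 6 of 7 cases (adjusted p = 1.46e-11, and 1.15e-05 with an estimated correlation), with the cytochrome CYP1B1 at 0.57 ± 0.06. Matrix genes fell in 12 of 20 cases (adjusted p = 2.13e-11, and 0.00224 with an estimated correlation). Adjusted over the list alone, 14 ER stress and 14 matrix genes fell, and 20 NRF2 and 6 AhR genes rose.

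Smaller list changes with poria at the high dose were falls in 3 of 5 metallothionein-list genes (adjusted p = 8.79e-07, and 0.00323 with an estimated correlation), 10 of 25 cholesterol synthesis genes (adjusted p = 1.54e-06, and 0.00791 with an estimated correlation), 9 of 20 hypoxia genes against 1 rise (adjusted p = 1.91e-06, and 0.00224 with an estimated correlation) and 9 of 24 lysosomal genes against 1 rise (adjusted p = 5.67e-06, and 0.0136 with an estimated correlation). ATF4 targets fell in 9 and rose in 2 of 20 cases (adjusted p = 0.00119, and 0.116 with an estimated correlation). When adjusted over the list alone, 3 metallothionein, 12 cholesterol, 10 hypoxia, 12 lysosomal and 11 ATF4 genes fell. NF-kB genes rose in 5 and fell in 2 of 18 cases without passing camera (5 and 5 adjusted over the list alone; adjusted p = 0.0776), CXCL8 rising by 0.88 ± 0.09 to 20.4 ± 0.81 CPM. Of the 2074 genes called, 926 rose and 1148 fell, and 49 and 12 changed at least 2-fold. The count was 1313 without vehicle replicate 1 and 1312 without poria high replicate 2, and 3583 when edgeR was fitted to the 2 groups alone.

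Poria at the medium dose changed 263 genes, 77 up and 186 down, and at the low dose 75, 21 up and 54 down. Without the filter on low counts the low dose gave 276 up and 236 down, so its excess of falls depended on the filter. At the medium dose ER stress genes fell in 10 of 16 cases (adjusted p = 2.53e-23, and 0.000784 with an estimated correlation), HERPUD1 at -0.70 ± 0.12. NRF2 targets rose in 7 of 20 (adjusted p = 9.38e-13, and 0.000784 with an estimated correlation), with AKR1B10 at 0.71 ± 0.11. For these lists, adjusted over the list alone, 12 ER stress genes fell and 11 NRF2 genes rose. At the low dose 5 of 20 early-response genes fell (7 adjusted over the list alone; adjusted p = 5.38e-07, and 0.013 with an estimated correlation), and 2 of 20 mitosis genes (6 adjusted over the list alone; adjusted p = 4.52e-06, and 0.0392 with an estimated correlation). No ER stress gene was called at the low dose (7 fell adjusted over the list alone), while the list passed as lower (adjusted p = 4.52e-06) but not with an estimated correlation (0.142). Between the high and the low dose, a comparison that leaves out the vehicle, 490 genes were higher and 498 lower at the high dose, TXNIP by 4.36 ± 0.08, and FAM13B changed by -0.92 ± 0.06. In this comparison 2 of 11 glucocorticoid-response genes, SGK1 and KLF9, were higher (2 adjusted over the list alone; adjusted p = 0.000468, and 0.00213 with an estimated correlation). These smaller counts were sensitive to single libraries. Leaving out each of the 6 libraries in turn gave 96 to 167 calls at the medium dose. At the low dose it gave 14, 24 and 32 without vehicle replicates 1, 2 and 3, and 27 without poria low replicate 3. Without poria low replicate 2 edgeR called 0, while 1272 genes had an unadjusted p under 0.05. Many genes pass an unadjusted threshold with no effect, so that number does not by itself show changes. DESeq2 called 196 in a fit of all 60 libraries and was not run without that replicate. Between doses the count was 592 without poria low replicate 2, 642 without its replicate 3, and 603, 611 and 656 without poria high replicates 1, 2 and 3.

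**Figure D2:**
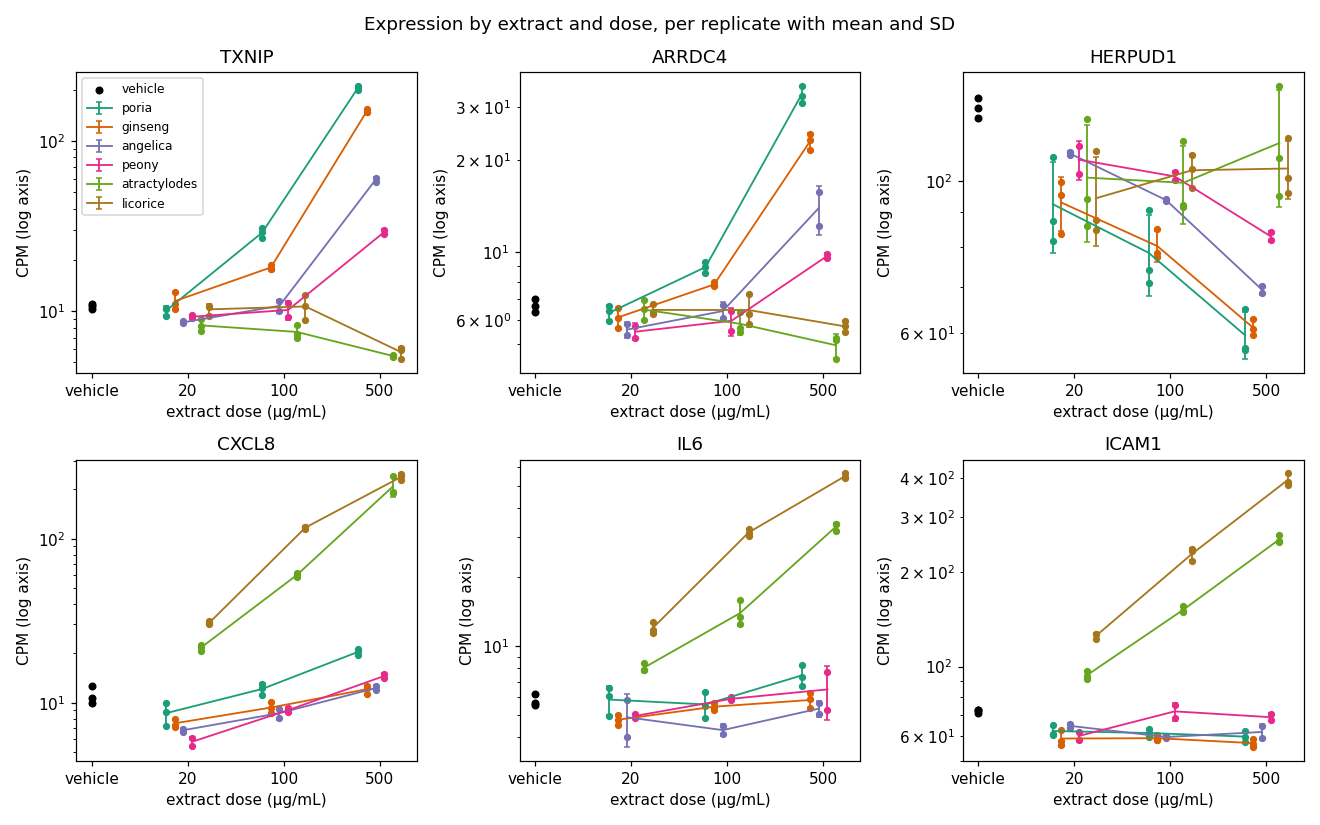
Level of 6 genes in CPM (log axis) against extract dose in µg/mL, with vehicle at the left; points are libraries, lines join group means and bars show the SD. TXNIP and ARRDC4 climb with poria, ginseng, angelica and peony, reaching 206 CPM of TXNIP with poria, while CXCL8, IL6 and ICAM1 climb with licorice and atractylodes, reaching 239 CPM of CXCL8 with licorice. CXCL8 also climbs from the low to the high dose of the other 4 extracts, to at most 20.4 CPM with poria.

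Atractylodes at the high dose raised inflammatory genes of the NF-kB pathway. Of 18 measured members 17 rose (18 adjusted over the list alone; adjusted p = 5.08e-63, and 7e-18 with an estimated correlation). CXCL8 rose from 11.1 ± 1.4 to 208 ± 28 CPM (4.23 ± 0.08, SD, n = 3), the cytokine IL6 (chromosome 7, 22725884 to 22732002) from 5.80 ± 0.36 to 33.2 ± 1.3 CPM (2.52 ± 0.10), the adhesion molecule ICAM1 (chromosome 19, 10270835 to 10286615) from 72.0 ± 0.98 to 255 ± 6.6 CPM (1.82 ± 0.04), and the superoxide dismutase SOD2 by 1.48 ± 0.05. CXCL1 (4.78 ± 0.34) and CXCL5 (2.91 ± 0.20) also rose, but CXCL1 has close paralogs, so its level is uncertain. Outside the list SERPINB2 rose by 2.38 ± 0.09, and the growth-factor early-response gene EGR3 (-1.50 ± 0.13), the integrin ITGB4 (-1.49 ± 0.11) and TXNIP (-0.97 ± 0.11) fell. The read-through gene CFAP298-TCP10L, which overlaps its neighbours and is uncertain, changed by -1.53 ± 0.33.

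With atractylodes at the high dose mitosis genes fell in 11 of 20 cases (11 adjusted over the list alone; adjusted p = 1.24e-06, and 0.0352 with an estimated correlation), KIF20A, a kinesin of cell division, at -0.32 ± 0.05. Several lists passed camera but not with an estimated correlation: interferon genes rose in 6 of 20 cases (adjusted p = 0.000376, and 0.435 with an estimated correlation). Cytosolic ribosomal protein genes rose in 6 of 20 (adjusted p = 0.000376, and 0.438 with an estimated correlation). Hypoxia genes rose in 6 of 20 (adjusted p = 0.00638, and 0.112 with an estimated correlation). Metallothionein-list genes rose in 2 of 5 (adjusted p = 0.00638, and 0.154 with an estimated correlation). Matrix genes fell in 7 and rose in 3 of 20 (adjusted p = 0.00179, and 0.174 with an estimated correlation). Astroglial markers fell in 2 of 10 (adjusted p = 0.00153, and 0.0599 with an estimated correlation), CLU at -0.27 ± 0.05. Adjusted over the list alone, 7 interferon, 9 ribosomal, 6 hypoxia and 4 metallothionein genes rose and 7 matrix and 5 astroglial genes fell. Epithelial, blood and endothelial markers fell in 2 of 7 cases (2 adjusted over the list alone; adjusted p = 0.00871, and 0.0352 with an estimated correlation), namely the keratins KRT18 at -0.51 ± 0.05 and KRT8 at -0.60 ± 0.09, which this line also expresses. Of the list members named by the rule, SLC1A3 (adjusted p = 0.0936), BST2 (0.192), BNIP3 (0.0543), PGK1 (0.0558), RPL7A (0.224), RPL13 (0.368) and RPS18 (0.447) lost their call without replicate 1, and PFKFB4 (0.101) without replicate 2. All 8 lost it in the 2 groups alone, and SLC1A3, BST2, RPL13 and RPS18 with the 5 libraries that stood apart left out, so these member counts rest on few libraries. The leukocyte marker PTPRC had 8.19 ± 0.64 CPM against 8.73 ± 0.30 in vehicle.

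In all, 1297 genes rose and 1188 fell with atractylodes at the high dose. Replicate 1 of this group stood apart from its other replicates, and the count was 905 without it, 1460 and 1423 without vehicle replicates 1 and 3, and 1481 with the 5 libraries that stood apart left out, and in the last of these fits the ribosomal list had an adjusted p of 0.265. Fitted to the 2 groups alone, edgeR called 586 genes.

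At the medium and low doses of atractylodes 190 and 144 genes changed. NF-kB inflammatory genes rose in 14 of 18 cases at the medium dose (15 adjusted over the list alone; adjusted p = 1.43e-55, and 5.91e-17 with an estimated correlation), and rose in 7 and fell in 2 of 18 at the low dose (7 and 2 adjusted over the list alone; adjusted p = 6.79e-07, and 0.000116 with an estimated correlation). CXCL8 rose by 2.44 ± 0.09 at the medium and by 0.97 ± 0.09 at the low dose, and ICAM1 by 1.08 ± 0.04 and 0.38 ± 0.04. EGR3 changed by -0.78 ± 0.12 and -0.68 ± 0.12. At the low dose 8 of 20 early-response genes fell (8 adjusted over the list alone; adjusted p = 7.32e-12, and 0.000525 with an estimated correlation). Between the high and the low dose 401 genes were higher and 333 lower at the high dose, including 17 of 18 NF-kB genes (17 adjusted over the list alone; adjusted p = 9.49e-84, and 5.03e-20 with an estimated correlation), CXCL8 by 3.27 ± 0.08. The counts moved by over 1.5 times without single libraries: at the medium dose to 84 without vehicle replicate 1 and to 122, 98 and 123 without replicates 1, 2 and 3 of the extract; at the low dose to 26, 59 and 66 without vehicle replicates 1, 2 and 3 and to 50 and 43 without replicates 2 and 3 of the extract. Between doses the count was 442 without high replicate 1 (291 higher and 151 lower) and 432 and 480 without low replicates 2 and 3, and 151 in the 2 groups alone (119 higher and 32 lower), so the near balance of both directions depended on the fit.

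Licorice at the high dose changed 5545 genes, 2849 up and 2696 down, with 241 and 177 changed at least 2-fold. NF-kB inflammatory genes rose in 17 of 18 cases (17 adjusted over the list alone; adjusted p = 1.46e-39, and 1.56e-14 with an estimated correlation): CXCL8 reached 239 ± 12 CPM (4.43 ± 0.08, SD, n = 3), ICAM1 395 ± 17 CPM (2.46 ± 0.04), SOD2 490 ± 15 CPM (2.17 ± 0.05) and IL6 54.9 ± 1.5 CPM (3.24 ± 0.09). The granulocyte growth factor CSF3 (chromosome 17, 40015361 to 40017813) rose by 6.04 ± 0.26 from 0.249 ± 0.12 to 16.8 ± 0.21 CPM. CXCL1, CXCL2 and CXCL3 rose by 5.23 ± 0.34, 3.89 ± 0.23 and 4.73 ± 0.26, though as close paralogs they may share reads and each is uncertain. Mitosis genes fell in 19 of 20 cases (adjusted p = 1.47e-22, and 1.14e-05 with an estimated correlation), KIF20A from 138 ± 5.1 to 70.5 ± 2.2 CPM and the kinase PLK1 at -0.84 ± 0.06. NRF2 targets rose in 16 and fell in 3 of 20 (adjusted p = 1.41e-10, and 0.00193 with an estimated correlation), HMOX1 at 0.77 ± 0.07. ATF4 targets rose in 15 and fell in 1 of 20 (adjusted p = 1.58e-08, and 0.00808 with an estimated correlation), the amino acid transporter subunit SLC3A2 at 0.86 ± 0.06. When adjusted over the list alone, 19 mitosis genes fell and 16 NRF2 and 15 ATF4 genes rose.

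Lysosomal genes rose in 14 of 24 cases with licorice at the high dose (adjusted p = 1.66e-06, and 0.011 with an estimated correlation), the autophagy receptor SQSTM1 from 559 ± 8.6 to 1530 ± 35 CPM. Cholesterol synthesis genes rose in 15 and fell in 3 of 25 (adjusted p = 2.32e-05, and 0.0189 with an estimated correlation). Metallothionein-list genes rose in 4 of 5 (adjusted p = 2.56e-05, and 0.0129 with an estimated correlation). Interferon genes rose in 18 of 20 (adjusted p = 8.48e-08, and 0.144 with an estimated correlation), ISG15 at 0.83 ± 0.12. Genes targeted by p53 rose in 7 and fell in 1 of 15 (adjusted p = 0.0116, and 0.066 with an estimated correlation). Hypoxia genes fell in 13 and rose in 2 of 20 (adjusted p = 4.69e-06, and 0.00415 with an estimated correlation), lactate dehydrogenase LDHA at -0.41 ± 0.04. Matrix genes fell in 12 and rose in 4 of 20 (adjusted p = 2.76e-05, and 0.0465 with an estimated correlation). Astroglial markers fell in 5 of 10 (adjusted p = 0.000346, and 0.0189 with an estimated correlation), among them VIM (-0.39 ± 0.06) and the glutamate transporter SLC1A3 (-0.39 ± 0.07). For these lists, adjusted over the list alone, 14 lysosomal, 16 cholesterol, 4 metallothionein, 18 interferon and 7 p53 genes rose, and 14 hypoxia, 12 matrix and 7 astroglial genes fell. Epithelial, blood and endothelial markers fell in 3 and rose in 1 of 7 (3 and 1 adjusted over the list alone; adjusted p = 0.0477, 0.0597 with an estimated correlation, 0.0524 with RLE scaling and 0.0548 with the replicate number as a block). PTPRC fell by 0.65 ± 0.11 to 5.58 ± 0.87 CPM. EGR3 changed by -1.37 ± 0.12.

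The medium dose of licorice changed 4519 genes, 2229 up and 2290 down, and the low dose 589, 274 up and 315 down. NF-kB genes rose in 16 of 18 cases at the medium dose (16 adjusted over the list alone; adjusted p = 1.03e-42, and 4.54e-15 with an estimated correlation) and in 14 of 18 at the low dose (15 adjusted over the list alone; adjusted p = 6.74e-37, and 4.7e-14 with an estimated correlation). CXCL8 rose by 3.40 ± 0.08 and 1.47 ± 0.09 and IL6 by 2.43 ± 0.10 and 1.04 ± 0.10. Mitosis genes fell in 8 and rose in 2 of 20 at the medium dose (8 and 2 adjusted over the list alone; adjusted p = 0.00807, and 0.265 with an estimated correlation). Between the high and the low dose 1617 genes were higher and 1638 lower at the high dose. All 20 mitosis genes were lower (20 adjusted over the list alone; adjusted p = 1.33e-26, and 2.25e-06 with an estimated correlation) and 17 of 18 NF-kB genes higher (17 adjusted over the list alone; adjusted p = 2.14e-40, and 1.11e-14 with an estimated correlation), CSF3 by 4.40 ± 0.22. Replicate 3 of the medium dose differed most from its other replicates, with ribosomal protein genes holding 5.41% of its counts against 4.64 and 4.51% in the others. The count at the medium dose was 2255 without it, 3055 with the 5 libraries that stood apart left out, and 2001 when edgeR was fitted to the 2 groups alone. That at the low dose was 191 and 263 without vehicle replicates 1 and 3, 315 and 162 without replicates 2 and 3 of the extract, and 2298 in the 2 groups alone.

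**Figure D3:**
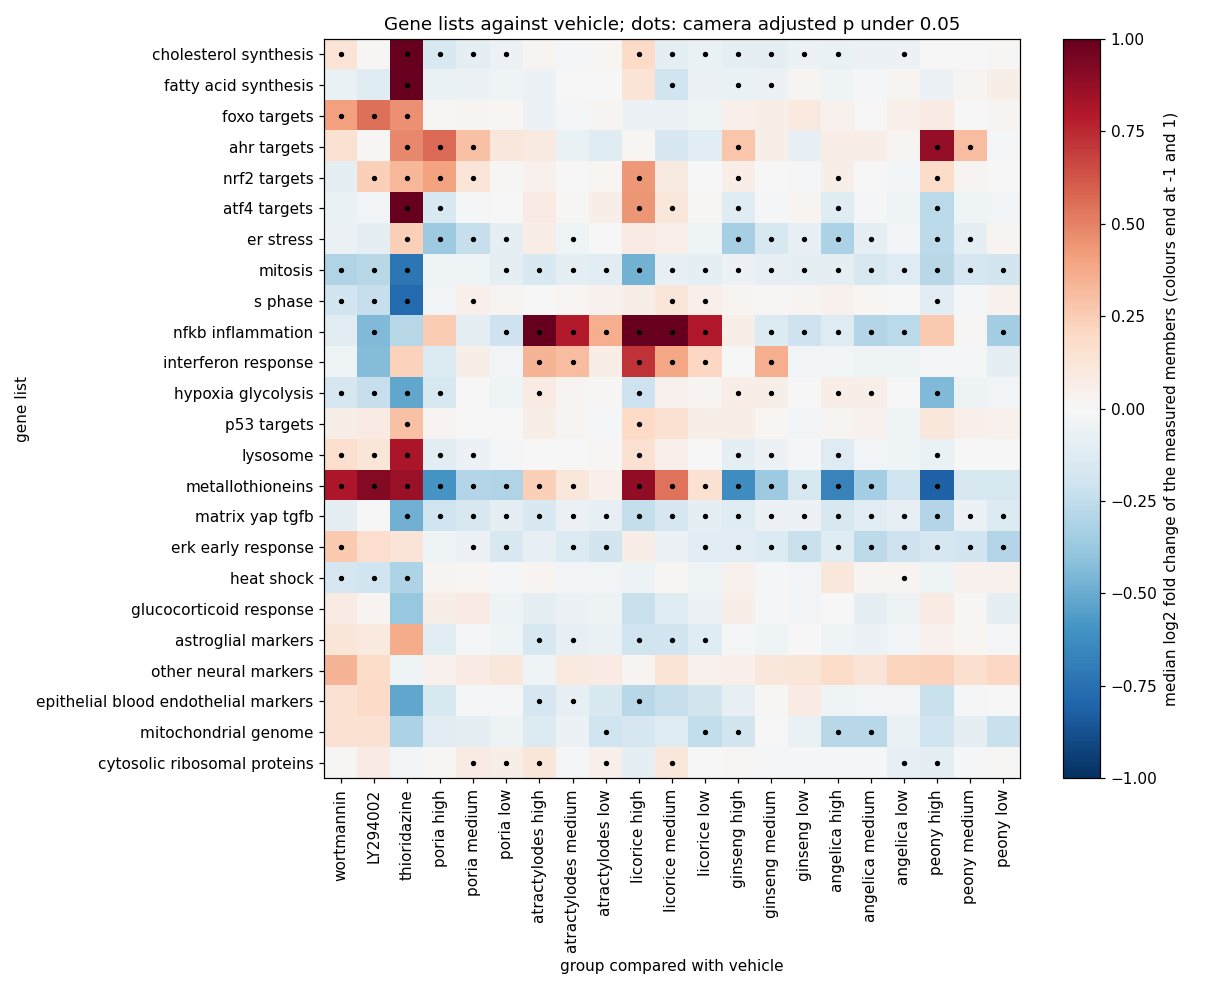
Median log2 fold change of the measured members of 24 gene lists (rows) in each group against vehicle (columns), red for higher and blue for lower, with dots where the camera adjusted p was under 0.05. The NF-kB list is red in the atractylodes and licorice columns, with a median of 2.32 for licorice at the high dose, and the ER stress list is blue in those of poria, ginseng, angelica and peony, with a median of -0.36 for poria at the high dose.

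Ginseng at the high dose raised TXNIP from 10.7 ± 0.33 to 150 ± 3.1 CPM (3.81 ± 0.08, SD, n = 3) and ARRDC4 by 1.79 ± 0.09. ER stress genes fell in 12 of 16 cases (14 adjusted over the list alone; adjusted p = 8.72e-29, and 0.000329 with an estimated correlation), HSPA5 at -0.65 ± 0.05, HERPUD1 at -1.07 ± 0.12 and the chaperone CALR at -0.32 ± 0.04. The stress-induced factor DDIT3 (-0.68 ± 0.08) and the kinase SIK1 (-0.87 ± 0.10) also fell. Matrix genes fell in 8 of 20 (adjusted p = 4.54e-08, and 0.0106 with an estimated correlation). Cholesterol synthesis genes fell in 7 of 25 (adjusted p = 7.37e-07, and 0.0106 with an estimated correlation), INSIG1 at -0.48 ± 0.05. Lysosomal genes fell in 7 of 24 (adjusted p = 7.52e-07, and 0.0106 with an estimated correlation). Metallothionein-list genes fell in 3 of 5 (adjusted p = 7.52e-07, and 0.00915 with an estimated correlation). AhR targets rose in 2 of 7 (adjusted p = 0.00261, and 0.0303 with an estimated correlation). NRF2 targets rose in 7 of 20 (adjusted p = 0.00331, and 0.144 with an estimated correlation), NQO1 at 0.33 ± 0.05. Adjusted over the list alone, 11 matrix, 12 cholesterol, 11 lysosomal and 4 metallothionein genes fell, and 4 AhR and 7 NRF2 genes rose.

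In all, 547 genes rose and 753 fell with ginseng at the high dose. Leaving out each of the 6 libraries in turn gave 623 to 859 calls, and EGR1 (0.67 ± 0.16) lost its call without ginseng high replicate 2 (adjusted p = 0.068) and in the 2 groups alone (adjusted p = 0.0551), as did UCA1 (-0.67 ± 0.15) without vehicle replicate 3 (adjusted p = 0.1). Fitted to the 2 groups alone, edgeR called 2975 genes.

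Ginseng at the medium dose changed 102 genes and at the low dose 106. At the medium dose TXNIP rose by 0.76 ± 0.09 and SIK1 changed by -0.56 ± 0.09. ER stress genes fell in 8 of 16 cases (12 adjusted over the list alone; adjusted p = 4.34e-18, and 0.00401 with an estimated correlation). At the low dose TXNIP had 11.5 ± 1.4 CPM (0.10 ± 0.10, adjusted p = 0.751), and PTGS2, which makes prostaglandins, fell by 0.49 ± 0.08. Of 18 NF-kB genes 5 fell at the low dose (8 adjusted over the list alone; adjusted p = 1.67e-09, and 3e-06 with an estimated correlation), as did 2 of 20 early-response genes (11 adjusted over the list alone; adjusted p = 2.54e-09, and 0.00319 with an estimated correlation). CXCL8 changed there by -0.56 ± 0.11, a call lost without vehicle replicate 2 (adjusted p = 0.0794) and without replicates 2 and 3 of the extract (0.0723 and 0.0707). The ER stress list was lower there too, with 0 of 16 genes called (2 adjusted over the list alone; adjusted p = 0.000159, 0.267 with an estimated correlation and 0.091 with fry). Between the high and the low dose 40 genes were higher and 77 lower at the high dose, TXNIP by 3.71 ± 0.08, and ER stress genes were lower in 10 of 16 cases (14 adjusted over the list alone; adjusted p = 1.66e-36, and 4.41e-05 with an estimated correlation), HERPUD1 losing its call without low replicate 1 (adjusted p = 0.0512). At the medium dose the count was 27, 32 and 39 without vehicle replicates 1, 2 and 3 and 35 and 19 without replicates 2 and 3 of the extract. At the low dose it was 11 to 39 without any of 5 libraries and 406 without ginseng low replicate 1, which stood apart. It was 1100 with the 5 libraries that stood apart left out. On principal component 4 ginseng low replicate 1, at -14.14, lay beside the vehicle libraries at -8.89 to -13.47. Replicates 2 and 3 of that dose were at -0.64 and -1.9. Leaving out a treated library that lies near vehicle can by itself raise the count. Between doses the count was 65, 58 and 66 without high replicates 1, 2 and 3 and 63 without low replicate 1.

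Angelica at the high dose, with 2 libraries, raised TXNIP from 10.7 ± 0.33 (n = 3) to 59.2 ± 2.3 CPM (SD, n = 2; 2.47 ± 0.09) and ARRDC4 by 1.07 ± 0.10. ER stress genes fell in 12 of 16 cases (14 adjusted over the list alone; adjusted p = 1e-23, and 0.00139 with an estimated correlation), HSPA5 at -0.60 ± 0.06 and PDIA4, a protein disulfide isomerase, at -0.38 ± 0.04. Matrix genes fell in 9 of 20 (adjusted p = 1.43e-09, and 0.00755 with an estimated correlation), the growth factor CCN2 at -0.78 ± 0.13. Lysosomal genes fell in 8 of 24 (adjusted p = 5.23e-07, and 0.00928 with an estimated correlation). Metallothionein-list genes fell in 3 of 5 (adjusted p = 5.23e-07, and 0.00738 with an estimated correlation). Cholesterol synthesis genes fell in 5 of 25 (adjusted p = 0.000898, and 0.0848 with an estimated correlation), and of 13 genes of the mitochondrial genome 1 fell (adjusted p = 0.00289, 0.398 with an estimated correlation and 0.126 with fry). That gene, MT-CO2, lost its call without replicate 1 or 2 of the extract (adjusted p = 0.12 and 0.255) and without vehicle replicate 1 or 2 (0.0833 and 0.0539). When adjusted over the list alone, 11 matrix, 11 lysosomal, 3 metallothionein, 7 cholesterol and 2 mitochondrial genes fell. The scaffold gene NEDD9 (-0.87 ± 0.15) fell and the reductase AKR1B10 (0.85 ± 0.13) rose. In all, 526 genes rose and 632 fell. The count was 620 without vehicle replicate 1, 401 and 264 without replicates 1 and 2 of the extract, and 2952 in the 2 groups alone. TNFRSF25 (0.79 ± 0.17) lost its call without angelica high replicate 1 (adjusted p = 0.0903).

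At the medium and low doses of angelica 522 and 313 genes changed. TXNIP had 10.7 ± 0.96 and 8.61 ± 0.17 CPM there, neither passing the test. CCL2 fell by 0.68 ± 0.10 at the medium dose, and PTGS2 fell by 0.71 ± 0.09 at the low dose. NF-kB genes fell in 6 of 18 cases at the medium dose (9 adjusted over the list alone; adjusted p = 4.59e-08, and 2.17e-05 with an estimated correlation) and in 6 of 18 at the low dose (7 adjusted over the list alone; adjusted p = 3.07e-10, and 1.38e-06 with an estimated correlation). At the low dose 4 of 20 early-response genes fell (9 adjusted over the list alone; adjusted p = 7.77e-09, and 0.00499 with an estimated correlation). Between the high and the low dose 69 genes were higher and 100 lower at the high dose, TXNIP by 2.78 ± 0.10. Fitted to these 2 groups alone, edgeR called 6 genes, 5 higher and 1 lower, so the count and its balance depended on the fit. Between doses ER stress genes were lower in 7 of 16 cases, and in 14 adjusted over the list alone (adjusted p = 5.1e-24, and 0.00128 with an estimated correlation). The count at the medium dose was 150, 335 and 344 without vehicle replicates 1, 2 and 3 and 60 and 117 without replicates 1 and 2 of the extract, and that at the low dose was 115 and 143 without vehicle replicates 1 and 2, 93 without low replicate 1, 280 without low replicate 2 and 757 with the 5 libraries that stood apart, low replicate 2 among them, left out. That replicate was chosen for its place beside the vehicle libraries on principal component 4, and 2 libraries cannot show which of them is the unusual one. Between doses it was 46 and 38 without high replicates 1 and 2, 847 without low replicate 1 and 37 without low replicate 2.

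Peony at the high dose, with 2 libraries, lowered genes of hypoxia and glycolysis. Of 20 measured members 17 fell and 1 rose (17 and 1 adjusted over the list alone; adjusted p = 8.24e-24, and 3.26e-08 with an estimated correlation), with BNIP3, a mitophagy receptor (chromosome 10, 131966455 to 131982013), going from 122 ± 4.0 (n = 3) to 54.5 ± 1.2 CPM (SD, n = 2; -1.17 ± 0.06), the collagen prolyl hydroxylase subunit P4HA1 at -0.63 ± 0.04 and the kinase PDK1 at -0.82 ± 0.07. AhR targets rose in 6 of 7 (adjusted p = 3.61e-11, and 1.94e-05 with an estimated correlation), CYP1B1 (chromosome 2, 38066973 to 38109902) from 117 ± 2.8 to 227 ± 10 CPM (0.96 ± 0.06), and NRF2 targets rose in 12 and fell in 1 of 20 (adjusted p = 6.54e-10, and 0.00175 with an estimated correlation), NQO1 at 0.88 ± 0.06. Matrix genes fell in 13 of 20 (adjusted p = 1.07e-13, and 0.000651 with an estimated correlation), ANKRD1, a YAP target, at -1.61 ± 0.17. Mitosis genes fell in 16 of 20 (adjusted p = 4.48e-13, and 0.000651 with an estimated correlation), TPX2 at -0.34 ± 0.05. ER stress genes fell in 12 of 16 (adjusted p = 5.16e-12, and 0.0117 with an estimated correlation). Metallothionein-list genes fell in 4 of 5 (adjusted p = 6.72e-08, and 0.00172 with an estimated correlation). ATF4 targets fell in 11 of 20 against 2 rises (adjusted p = 1.24e-05, and 0.0381 with an estimated correlation). For these lists, adjusted over the list alone, 6 AhR and 15 NRF2 genes rose and 15 matrix, 19 mitosis, 13 ER stress, 4 metallothionein and 12 ATF4 genes fell.

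TXNIP rose by 1.45 ± 0.09 to 29.2 ± 1.3 CPM with peony at the high dose. NF-kB genes rose in 7 and fell in 3 of 18 cases without passing camera (8 and 3 adjusted over the list alone; adjusted p = 0.0848), CXCL8 rising by 0.39 ± 0.11 to 14.6 ± 0.57 CPM. Other large changes were the neuronal pentraxin NPTX1 (2.16 ± 0.11, from 4.54 ± 0.59 to 20.3 ± 1.0 CPM), the receptor gene VIPR1 (1.67 ± 0.15), THBD (1.53 ± 0.10), the long RNA UCA1 (-1.92 ± 0.21) and ID2 and ID3 (-1.44 ± 0.10 and -1.43 ± 0.12), inhibitors of helix-loop-helix factors that BMP signalling induces. Markers of other neural cells did not pass camera (2 of 9 rose, 3 adjusted over the list alone; adjusted p = 0.0848), with MBP at 0.66 ± 0.11. Of 10 astroglial markers 4 rose and 4 fell (5 and 4 adjusted over the list alone; adjusted p = 0.545), SOX9 at -0.38 ± 0.06 and CHI3L1 at 0.24 ± 0.05.

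In all, 1848 genes rose and 1862 fell with peony at the high dose, 508 and 28 of them at least 2-fold. The 2-fold counts were not repeated without replicate 1, so their excess of rises may rest on that library. Replicate 1 had the lowest total count, 19.45 M, yet 37765 genes with at least 1 count, against 22528 to 23832 in the other libraries; 6351 genes were counted in that library and in no other, with a median count of 2. The count of calls was 1354 without it, 6326 without replicate 2 (3999 higher and 2327 lower), and 2061 with the 5 libraries that stood apart left out.

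**Figure D4:**
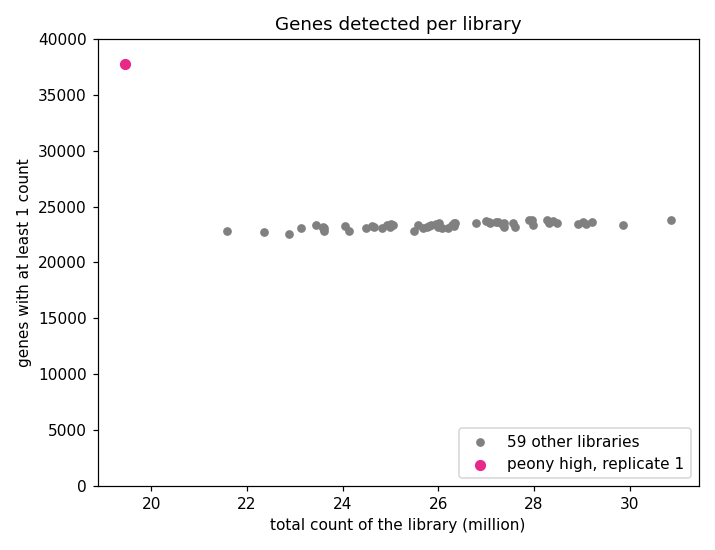
Genes with at least 1 count in each library against the total count of the library in M counts. Peony high replicate 1 lies at 37765 genes and 19.45 M counts, apart from the other 59 libraries, which lie between 22528 and 23832 genes.

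The medium dose of peony changed 457 genes and the low dose 937. ID3 fell by 0.74 ± 0.12 at the medium dose, CYP1B1 rose by 0.33 ± 0.06 there, and mitosis genes fell in 8 of 20 cases (12 adjusted over the list alone; adjusted p = 1.56e-12, and 0.00227 with an estimated correlation). At the low dose mitosis genes fell in 8 of 20 (11 adjusted over the list alone; adjusted p = 2.34e-11, and 0.00169 with an estimated correlation). Early-response genes fell in 8 of 20 (14 adjusted over the list alone; adjusted p = 1.13e-13, and 0.000181 with an estimated correlation). NF-kB genes fell in 7 of 18 (9 adjusted over the list alone; adjusted p = 5.92e-11, and 1.08e-06 with an estimated correlation), CXCL8 by -0.93 ± 0.13, while NEAT1 rose by 1.01 ± 0.15. Between the high and the low dose 498 genes were higher and 560 lower at the high dose; 17 of 20 hypoxia genes were lower and 1 higher (18 and 1 adjusted over the list alone; adjusted p = 3.82e-32, and 6.9e-10 with an estimated correlation), NPTX1 differed by 1.88 ± 0.12 and SAMD11 by -1.46 ± 0.08. The count at the medium dose was 226, 288 and 303 without vehicle replicates 1, 2 and 3 and 84 and 102 without replicates 1 and 2 of the extract, and that at the low dose was 451 without vehicle replicate 1 and 172 and 249 without replicates 1 and 2 of the extract. Between doses it was 402 without high replicate 1, 4081 without high replicate 2 (2926 higher and 1155 lower), 455 and 495 without low replicates 1 and 2, and 610 with the 5 libraries that stood apart left out.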

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

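Of the tests below, those of whether the vehicle libraries stood apart were chosen after the results were seen, and the reading of the blood cell, vehicle chance and sample code tests was changed after their values were seen.

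The change from the low to the high dose differed among the 6 extracts for 2903 genes by edgeR's quasi-likelihood test of the difference. Poria and atractylodes differed for 632 genes (TXNIP by 4.95 ± 0.14, CXCL8 by -2.03 ± 0.13), licorice and ginseng for 2400 (TXNIP by -4.55 ± 0.13, CXCL8 by 2.27 ± 0.13), and angelica and peony for 168 (TXNIP by 1.13 ± 0.15, with CXCL8 at -0.47 ± 0.19, adjusted p = 0.329).

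TXNIP and ARRDC4 rose and ER stress genes fell with poria, ginseng and angelica at the high dose. Vehicle libraries that stood apart would leave no difference between doses, yet TXNIP was higher at the high than at the low dose by at least 2.78 in these 3 extracts. Between doses 11, 10 and 7 of 16 ER stress genes were lower with poria, ginseng and angelica, so vehicle alone does not give that fall either. It could give part of it, since HERPUD1 had 92.5 to 110 CPM at the low doses of all 6 extracts against 128 in vehicle. HERPUD1 also varied with the replicate number in the extract groups of 3 libraries, where replicate 1 was highest. One hypothesis is that the extracts carry sugar, since TXNIP is induced by glucose and L-15 medium supplies galactose in its place. It was then asked of peony, whose ER stress genes also fell, and TXNIP rose there by 1.45 ± 0.09, as sugar would need. At the high doses of licorice and atractylodes TXNIP had 5.74 and 5.46 CPM against 10.7 in vehicle. A rise was therefore not shared by all extracts. Such a rise does not single out sugar, since LY294002 and wortmannin raised TXNIP by 1.68 ± 0.08 and 1.15 ± 0.09. Neither the sugar content of the extracts nor of the medium was measured, so sugar stays open beside other constituents of the extracts, which were not tested.

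NF-kB inflammatory genes rose with atractylodes and licorice. Vehicle libraries that stood apart would leave few differences between doses, yet 17 of 18 members were higher at the high dose in both extracts. Blood cells in the cultures had been expected to show PTPRC above 1 CPM, which was met at 8.19 CPM in atractylodes and 5.58 in licorice, but vehicle had 8.73 CPM, so that the condition was a poor one. CD68, a macrophage marker that is also a lysosomal gene, had 169 CPM in vehicle, 150 in atractylodes high and 224 in licorice high. At these high doses AIF1 and LYZ, abundant in macrophages and monocytes, had group means of at most 0.0144 CPM and 0.0433 CPM in the highest library, which argues against such cells as the source. Endotoxin carried by the extracts stays open. In vehicle its receptor TLR4 had 17.2 CPM and its partner LY96 8.89, with their co-receptor CD14 at 0.485. RNA of a receptor does not show that the line responds to endotoxin, and no such response was measured. Neither endotoxin nor the composition of the extracts was measured, and a response to constituents of the plants stays open as well.

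Mitosis and early-response genes were lower than vehicle at the low dose of all 6 extracts by camera, a call lost for licorice with an estimated correlation (adjusted p = 0.0975 for both lists). These comparisons share 3 vehicle libraries, so a chance deviation of those was simulated 100 times. Over all genes tested the mean covariance of the 6 changes was 0.0382 against 0.0254 to 0.0312 in the simulations. Values above the simulations, over all genes and over both lists, had been taken beforehand to exclude chance, and over both lists the members' mean product was 0.0436 against 0.00124 to 0.0243, so that both conditions were met. The lists were picked for being lower, though, and the simulations drew genes independently, so that a deviation shared by many genes could exceed them and chance in the vehicle libraries stays open. Covariance within a set of sample codes exceeded that between sets by 0.00121, just under the highest simulated difference of 0.00134, so a difference between sets cannot be told apart from none. The sample titles name the same batch for all samples, but the vehicle is alone in its code set. A difference in handling between vehicle and extracts could therefore give the same pattern. So could a difference in solvent, since a DMSO content was recorded here for the vehicle only. Both were not tested and stay open beside an effect that all extracts share. The same doubt holds for the NF-kB list, which was lower than the same vehicle libraries at the low doses of poria, ginseng, angelica and peony (adjusted p = 5.91e-05, 1.67e-09, 3.07e-10 and 5.92e-11) and was not part of these tests. It holds also for the matrix list, not tested here either. That list passed camera against vehicle at the low doses of atractylodes, licorice, ginseng, angelica and peony. With an estimated correlation it did not pass there (adjusted p = 0.435, 0.142, 0.12, 0.0935 and 0.0584). The doubt extends to the cholesterol list, which passed camera against vehicle at the low doses of poria, licorice, ginseng and angelica. The metallothionein list passed at those of licorice and ginseng. Neither passed there by camera with an estimated correlation (adjusted p = 0.257, 0.231, 0.168 and 0.244, then 0.269 and 0.267). Changes of both lists at the high doses are given here against vehicle only.

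For comparisons of 3 against 3 libraries, 10 splits are too few for a share under 0.05. In the fit of the 2 groups alone the real split gave 7368 calls for wortmannin (highest other split 0), 7185 for LY294002 (0), 9567 for thioridazine (0) and 2962 between both inhibitors (1). At the high, medium and low dose it gave 3583, 1107 and 752 for poria (highest others 2, 2 and 4), 586, 701 and 458 for atractylodes (0, 5 and 1), 6655, 2001 and 2298 for licorice (0, 0 and 1), and 2975, 600 and 60 for ginseng (1, 8 and 110). Between doses it gave 1401 for poria (3), 151 for atractylodes (1), 4171 for licorice (1) and 59 for ginseng (3). As many calls came from 1 of 10 splits, the real one, in each of these except the low dose of ginseng, where 2 of 10 splits did.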

How the results depend on the processing

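Leaving out the 5 libraries that stood apart was chosen after the data were seen; the other alternatives were fixed before the data were examined. With RLE size factors 28 of 28 counts stayed within 1.5 times, and no call of a named gene reversed under any alternative. Of 352 calls of named genes, each gene counted once per comparison, 352 were kept with RLE and with the replicate number as a block, 351 without the filter and 337 in the 2 groups alone, 345 of 345 were with DESeq2, 100 of 2020 were lost with a library left out and 6 of 88 with the 5 libraries left out. DESeq2 gave no adjusted p for the named-gene calls beyond these 345, and those were left out of its count. Of 283 list calls, 138 were lost with an estimated correlation, 44 with fry, 2 with RLE and 1 with the replicate block. With the 5 libraries left out, 19 of 95 list calls were lost and 2 reversed: ribosomal proteins between doses of atractylodes (adjusted p = 0.147) and the mitochondrial genome between doses of angelica (adjusted p = 0.289); the cause was not tested.

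Counts moved by over 1.5 times as follows, and the cause was not tested. With the replicate number as a block, the low doses of poria, atractylodes, ginseng and angelica gave 128, 251, 188 and 491 calls. Ginseng medium gave 169, and every count rose with the block. Deviations from the group mean in libraries of the same replicate number had correlations of -0.07 to 0.05, and 0.22 once. These run over all genes tested, so they do not exclude that some genes followed the replicate number. HERPUD1 did so in part, being highest in replicate 1 in every extract group of 3 libraries. At the low dose of poria its replicates 1, 2 and 3 had 108.3, 87.48 and 81.74 CPM. The vehicle replicates ran the other way, with 123.6, 128 and 132.2 CPM. Without the filter, poria medium and low gave 592 and 512, atractylodes medium and low 406 and 652, ginseng medium and low 312 and 328, angelica medium 887, and the dose contrasts of ginseng and angelica 225 and 375. With DESeq2 the low doses of poria, atractylodes and ginseng gave 196, 379 and 230, ginseng medium 243, angelica medium 803 and the dose contrast of angelica 313. Of the 5 libraries that stood apart, ginseng low replicate 1 and angelica low replicate 2 lay beside vehicle on principal component 4. With the 5 libraries left out, atractylodes high gave 1481, ginseng low 1100, angelica low 757, peony high 2061, and the dose contrasts of angelica and peony 93 and 610. Angelica low then had 41.5% of its calls higher, against 60.4% in all libraries and 40.9 and 48.9% without its replicates 1 and 2.

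In the 2 groups alone, high, medium and low doses gave 3583, 1107 and 752 for poria, 586, 701 and 458 for atractylodes, and 2975, 600 and 60 for ginseng. Licorice medium and low gave 2001 and 2298, angelica 2952, 2219 and 102, and peony medium and low 1868 and 2628. The dose contrasts of atractylodes, ginseng, angelica and peony gave 151, 59, 6 and 650. Such fits have fewer libraries from which to estimate the spread.

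With each library left out in turn, counts ran from 4790 to 4939 for wortmannin, 6017 to 6515 for LY294002, 7855 to 8050 for thioridazine and 2008 to 2782 between both inhibitors. At the high, medium and low dose they ran from 1312 to 1536, 96 to 167 and 0 to 57 for poria, 905 to 2977, 84 to 136 and 26 to 210 for atractylodes, 4361 to 4936, 2255 to 4826 and 162 to 417 for licorice, and 623 to 859, 19 to 79 and 11 to 406 for ginseng. For angelica they ran from 264 to 815, 60 to 344 and 93 to 280, and for peony from 1354 to 6326, 84 to 303 and 172 to 656. Between doses they ran from 592 to 661 for poria, 432 to 888 for atractylodes, 2483 to 2815 for licorice, 58 to 80 for ginseng, 37 to 847 for angelica and 402 to 4081 for peony. The 0 was edgeR's count for poria low without its replicate 2, where 1272 genes had an unadjusted p under 0.05. That number does not by itself show changes, since many genes pass an unadjusted threshold with no effect. DESeq2 called 196 in all libraries and was not run without that replicate. Where a library left out of a pair left 1, that one was assumed to vary like the other groups.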

Other observations

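The change from the low to the high dose of one extract shares no library with that of another, so the extracts can be set side by side. Libraries that stood apart were included, and the correlations were not recomputed without them. Ginseng low replicate 1 and angelica low replicate 2 deviated alike on principal component 4 (-14.14 and -13.35). Such a shared deviation could raise the correlation of that pair. Across 11229 genes of at least 5 CPM, the changes of poria and ginseng had a Pearson correlation of 0.59 (Spearman 0.53), ginseng and angelica 0.58 (0.54), atractylodes and licorice 0.53 (0.35), poria and peony 0.50 (0.48) and poria and angelica 0.47 (0.43), while licorice and ginseng had -0.21 (-0.25). Over all 17919 genes tested the Pearson correlations of these pairs, in the same order, were 0.09, 0.06, 0.13, 0.15, 0.13 and -0.02. The drugs were given at 1 dose, so their changes against vehicle were used. Across the genes of at least 5 CPM the dose change of licorice had 0.26 (0.24) with the change by thioridazine, and that of atractylodes -0.20 (-0.17) with the change by LY294002. Over all genes tested these were 0.11 and -0.04. Genes are not independent replicates, and no p was computed for the 33 pairs.

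Peony high replicate 1 had 18510 genes with at least 10 counts, against 15510 to 16305 in the other libraries. The first 4 principal components held 12.5, 9.5, 5.1 and 3.9% of the variance.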
